A study of Rattus norvegicus with 12 samples.

How the data were processed

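Total RNA from the gastrocnemius of 12 rats was hybridised by the study's core facility to one-colour Affymetrix arrays, 1 per rat, in 4 groups of 3: vehicle or nandrolone for 7 days, with tissue taken at day 7 or day 35 after nerve section. The deposited values are linear signal intensities per probe set; per the labels they were made with MAS5, whose version, scaling target and detection filter are not given. The intensities were tested on the values: array medians and means differ, so no common scale is visible. A second deposited table, which its header calls fold changes from geometric means, holds 12 columns named only by number, with no key to the samples, and was not used. Groups were taken from the sample titles.

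The table held 31099 probe sets. The 57 control probe sets were left out, which leaves 31042. Signals were kept on the deposited scale, 16 was added and log2 taken. The 40% of probe sets with the lowest mean over all arrays were left out and 18626 were tested. The platform's annotation names 1 gene for 20826 probe sets, several for 436 and none for 9780; of those with 1 gene, 20758 had a gene ID in the RefSeq table of the GRCr8 assembly, which was used for current symbols only, with no coordinates. Of the tested probe sets 14322 named 1 gene, 10425 genes in all, and a gene is represented by its probe set with the highest mean.

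Limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8) fitted 4 group means with empirical Bayes moderation and an intensity trend, so that all groups share one estimate of the spread with 8 residual degrees of freedom. The 5 contrasts were nandrolone against vehicle at day 7 and at day 35, day 35 against day 7 under vehicle and under nandrolone, and the interaction. Tests were two-sided with Benjamini-Hochberg adjustment over all tested probe sets at 0.05. The number of arrays, 3 per group, limits the precision; an exact permutation test of 3 against 3 cannot go below 0.1.

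The 32 gene lists cover atrophy ubiquitin ligases and FoxO, proteasome subunits, the neuromuscular junction, myogenic regulators, slow and fast fibre genes, developmental muscle genes, oxidative phosphorylation, glycolysis and glycogen, fatty acid oxidation, extracellular matrix, cell cycle, androgen responsive, glucocorticoid responsive, Notch, Wnt, calcineurin and NFAT, circadian clock, denervation stress, immediate early and heat shock, interferon and ribosomal genes. A further 10 of the 32 hold markers of macrophages, lymphocytes, mast cells, Schwann cells and nerve, adipocytes, endothelium, smooth muscle and pericytes, fibroblasts, erythrocytes, and tendon and cartilage. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a contrast; fry gave no adjusted p under 0.349. Array scores of a list are the median of its genes' quantile-normalized, gene-centred log2 signals.

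Genes named in the text were taken by rule: up to 10 rises and 10 falls with the largest change among called genes whose arrays separate, up to 4 per list by smallest p, a fixed set of muscle and androgen genes, and, where few genes passed, those with the smallest p. The comparisons, tests, lists, naming rule and main alternatives were chosen before the data were examined. Because the deposited scale turned out not to be common to the arrays, values after quantile normalization stand beside the main ones.

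Alternatives were a pseudocount of 1 or 64, no filter or a 60% filter, quantile normalization, median centring, no trend, array quality weights, the replicate number as a block, an adjusted p of 0.10, a 1.5-fold minimum, a fit of only the 2 groups compared, the mean over a gene's probe sets, and each array of the groups compared left out in turn. Chosen after seeing the data were quantile normalization together with weights, with the block or without nandrolone day 35 replicate 3, and leaving that array out of the shared spread. Whether equal replicate numbers pair arrays was checked by correlating their group-centred log2 signals: only in the 2 nandrolone groups was every r above 0.1, at 0.173, 0.268 and 0.425, so the blocked count stands beside that comparison.

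The pipeline was tested on simulated data with the real groups and spread, in which 200 of 18626 probe sets were changed. With the arrays' own offsets it recovered 78% of 4-fold and 2% of 2-fold changes for nandrolone at day 7, 74% and 8% at day 35, 76% and 3% for time under vehicle and 71% and 2% for time under nandrolone, with none of the wrong sign. After quantile normalization of the same data these were 88% and 24%, 87% and 12%, 86% and 17%, and 80% and 16%. False calls numbered 5, 7, 4 and 11 on the deposited scale and 7, 3, 3 and 11 after quantile normalization. In 20 draws with the matrix list raised by 0.5, camera called that list 20 times and unchanged lists 4 times in all. Genes were simulated as independent and these 20 draws had no array offsets. They therefore do not test camera where genes move together or where arrays differ in scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.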

Results

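Gene expression was measured in the gastrocnemius, a calf muscle, of male Wistar-Hannover rats whose left sciatic nerve had been cut, which takes away the muscle's motor supply. The rats received nandrolone, an anabolic androgen, or vehicle for 7 days and were killed at day 7, with dosing begun at surgery, or at day 35, with dosing begun 29 days after it. Each of the 4 groups held 3 rats with 1 Affymetrix array each, 12 arrays in all, and no innervated muscle was among them. Median signals ranged from 44.8 in vehicle day 35 replicate 2 to 111 in nandrolone day 35 replicate 3, and the next highest was 63.5. That last array also stood apart in correlation, with a mean Pearson r of 0.900 with the other arrays of its group. The 3' to 5' signal ratio of the actin control, a sign of RNA quality, was lowest in the same array at 1.9 and highest in vehicle day 35 replicate 3 at 3.71. At day 35 it did not overlap between the treatments, with 3.13, 2.68 and 3.71 under vehicle and 2.57, 2.12 and 1.9 under nandrolone. The number of arrays limits the precision of every value below. Values after ± are standard errors from limma with 3 arrays per group, and changes are on the log2 scale. Because arrays differed in scale, the median change over all 18626 tested probe sets was 0.13 for nandrolone at day 7, 0.26 for nandrolone at day 35, 0.04 for time under vehicle, 0.20 for time under nandrolone and 0.13 for the interaction. List medians are given relative to these shifts in every comparison except time under vehicle and the interaction.

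The first comparison asked how denervated muscle without the drug differed between day 35 and day 7. With no innervated muscle at either day, age or growth over that time cannot be told apart from time after nerve section. Calml3, a calmodulin-like calcium sensor, rose by 4.37 ± 0.41, from a geometric mean signal of 15.9 to 646; its day 7 signal is near background, and the change was 5.26 with a pseudocount of 1 and 3.15 with 64. Cdkn1c, an inhibitor of cyclin-dependent kinases, rose by 3.51 ± 0.42, and Fxyd6, a regulator of the sodium pump, by 3.00 ± 0.36. Clock genes rose with them: Per3 by 2.60 ± 0.45 and Per2 by 2.15 ± 0.39, both repressors of the circadian cycle. Nfkbia, the inhibitor that holds NF-kappaB in the cytoplasm, rose by 2.33 ± 0.37 and the integrin subunit Itga9 by 2.18 ± 0.28. Among the genes that fell were Rcan1, an inhibitor of the calcium-dependent phosphatase calcineurin, by -2.28 ± 0.38, the adhesion receptor gene Pvr by -2.42 ± 0.46 and the tubulin gene Tuba4a by -2.07 ± 0.42.

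In all, 192 probe sets passed limma at an adjusted p of 0.05, 148 higher and 44 lower at day 35, and 2721 had an unadjusted p under 0.05. The called probe sets named 87 genes that rose and 31 that fell. In each of the 192 the 3 arrays of one day lay above the 3 of the other, which held for 27.6% of all tested probe sets against 10% by chance. Mtarc1, a mitochondrial reductase gene, rose by 2.09 ± 0.35, Ppl, an intermediate filament linker, by 2.73 ± 0.40 and the adaptor gene Stap2 by 2.56 ± 0.36. The day 7 signals of Ppl and Stap2, 9.12 and 12.1, are near background, and their changes were 3.99 and 3.64 with a pseudocount of 1 and 1.56 and 1.48 with 64. The other falls named by rule were Magea9 by -2.62 ± 0.51, LOC100912188 by -2.08 ± 0.34, the autophagy gene Vmp1 by -1.56 ± 0.28, Fam13a by -1.55 ± 0.32, Prxl2b by -1.51 ± 0.33, Pals2 by -1.40 ± 0.27 and the cap-binding protein gene Eif4e2 by -1.37 ± 0.29. The changes of Magea9, whose day 35 signal of 20.3 is near background, were -3.37 with a pseudocount of 1 and -1.67 with 64. Calml3, Cdkn1c, Fxyd6, Itga9, Rcan2 and Bhlhe41 kept their calls under all 18 alternatives run for single genes. Other genes kept theirs in fewer: Chrne in 9, Fst in 10, Lamb2, Klf9, Tuba4a, Eif4e2, Prxl2b and Fam13a in 11, Klf15, Myh1, Magea9 and Pals2 in 12, Per2, Pvr and Mtarc1 in 13, Per3, Dbp, Erbb2, Rcan1 and Vmp1 in 14, and Nfkbia, Ppl, Stap2 and LOC100912188 in 16. For Ppl, Stap2, Magea9 and Fam13a these counts are out of 17 alternatives. Most losses came on leaving out 1 array.

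**Figure D1:**
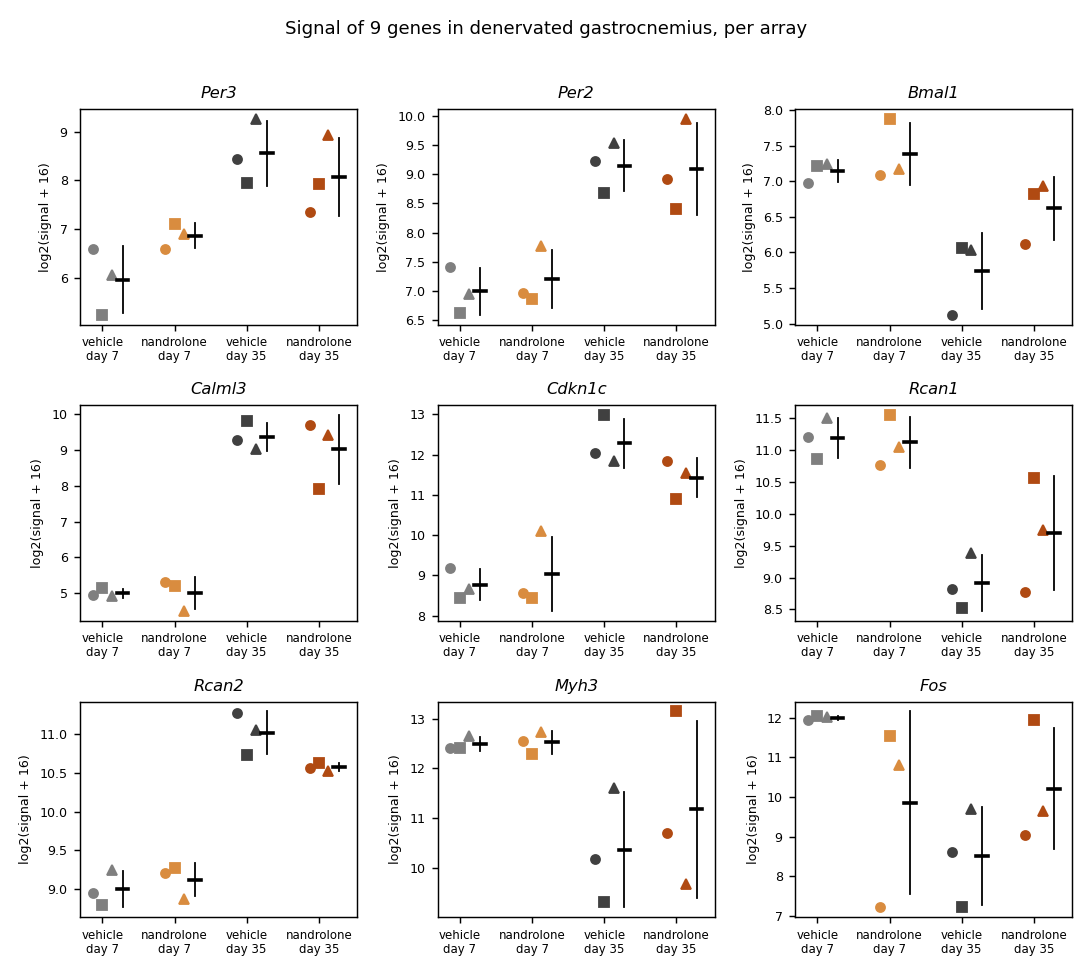
Log2(signal + 16) of 9 genes on each of the 12 arrays, by group; circles, squares and triangles are replicates 1, 2 and 3, and the bar and line beside them are the group mean and SD (n = 3). The 3 day 35 arrays lie above the 3 day 7 arrays for Calml3, Per3, Per2, Cdkn1c and Rcan2 under both treatments, while Fos varies widely within every group but vehicle day 7, and Myh3 within the 2 day 35 groups.

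Of the 17 tested circadian clock genes 5 rose over all probe sets and none fell: Per3, Per2, Bhlhe41 by 1.88 ± 0.26, the clock output activator Dbp by 1.61 ± 0.28 and its relative Tef by 1.14. Further probe sets of Tef stood at 0.43 and 0.27 and did not pass. Adjusted over the list alone, 8 were higher and 3 lower, and the 3 lower were Bmal1, a core activator of the cycle, at -1.40 ± 0.34, its partner Npas2 at -0.95 and the repressor of Dbp targets Nfil3 at -1.67. As a set the list was higher by camera, with a median of 0.81 (adjusted p = 0.000439). That call was lost with an estimated correlation (adjusted p = 0.751 with an estimated correlation).

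Of 18 tested neuromuscular junction genes, 3 rose over all probe sets: the receptor gene Erbb2 by 1.72 ± 0.31, Chrne, the adult subunit of the acetylcholine receptor, 2.82-fold (adjusted p = 0.0272), and the synaptic laminin gene Lamb2 by 1.40 ± 0.29. Adjusted over the list alone, 5 were higher, with Dok7 and Chrnb1 added, and Chrnd was lower at -1.70; the list did not move as a set (camera adjusted p = 0.246). Chrne lost its call after quantile normalization (adjusted p = 0.0643). Of the 14 calcineurin and NFAT genes, Rcan2 rose by 2.03 ± 0.22 while Rcan1 fell, and both encode regulators of calcineurin. A further probe set of Rcan2 stood at 1.11 and did not pass. Adjusted over the list alone 3 were higher and 2 lower, and the list did not pass camera. Among the 20 glucocorticoid responsive genes, the transcription factor genes Klf15 and Klf9 rose by 1.06 ± 0.22 and 0.99 ± 0.22. A further probe set of each gene did not pass, at 0.61 for Klf15 and 0.47 for Klf9. Adjusted over the list alone 5 were higher, including the kinase gene Sgk1 at 0.99, and Mt2A was lower; the list was higher as a set (median 0.64, camera adjusted p = 0.00708; adjusted p = 0.961 with an estimated correlation).

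Developmental muscle genes were lower at day 35 as a set, with a median of -1.07 over 11 genes (camera adjusted p = 1.6e-05). No member passed over all probe sets. Adjusted over the list alone 5 were lower, among them the embryonic and neonatal myosin heavy chains Myh3 at -2.12 ± 0.67 and Myh8 at -2.11 ± 0.73 and the growth factor gene Igf2 at -1.18 ± 0.29. Slow fibre genes were lower with a median of -0.73 over 14 genes (camera adjusted p = 7.1e-05), denervation stress genes with -0.51 over 18 and immediate early and heat shock genes with -0.76 over 16. Ankrd2, a stretch-responsive gene of slow fibres, stood at -4.72 ± 1.14 and Fos, an immediate early transcription factor, at -3.48 ± 0.94; each passed adjusted over the list alone, as did 4, 6 and 3 members of these lists, all lower. The calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.751 with an estimated correlation for each). The fast myosin gene Myh1 fell by -1.21 ± 0.23, the only fast fibre gene of 16 to pass. The denervation stress list shares 9 of its 18 tested genes with other lists, and the glucocorticoid list 7 of its 20.

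Further lists were lower by camera. Macrophage markers had a median of -0.61, with all 19 genes below 0 and none past the test; cell cycle genes had -0.52, extracellular matrix genes -0.35, proteasome subunits -0.12 and ribosomal proteins -0.05. After quantile normalization the proteasome call was lost (adjusted p = 0.171) and the relative median of ribosomal proteins was 0.03 (adjusted p = 0.723), and with the 60% filter that of cell cycle genes was 0.09 (adjusted p = 0.781). Without vehicle day 35 replicate 1 the matrix call was lost at -0.30, the proteasome call at -0.11 and the ribosomal call at -0.07. With an estimated correlation none of these held (adjusted p = 0.961 with an estimated correlation for macrophage markers and cell cycle genes, 0.972 for the other lists). The lists that passed camera numbered 11 of 29. Lists that passed it in no comparison gave these medians here: -0.02 for androgen responsive and anabolic genes, 0.04 for Wnt signalling, 0.09 for interferon and antigen presentation, -0.01 for glycolysis and glycogen and 0.16 for fibroblast markers. In the androgen responsive list Fst, an antagonist of myostatin, rose by 1.42 ± 0.29; after quantile normalization the value was 1.34 and the call was lost (adjusted p = 0.0616). Too few genes were tested for a set test of lymphocyte markers (median -0.39 over 4), mast cell markers (0.17 over 3) and erythrocyte markers (-1.31 over 3).

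The count of calls depended on scale and on single arrays. It was 1045 after quantile normalization, with 185 of the 192 among them, and 877 when nandrolone day 35 replicate 3, which is in neither group, was left out of the shared spread. It was 36, 13 and 22 without vehicle day 7 replicates 1, 2 and 3, and 42 and 74 without vehicle day 35 replicates 1 and 3. The excess of rises over falls also moved. Higher and lower calls were 641 and 404 after quantile normalization, 474 and 425 after median centring, and 35 and 39 without vehicle day 35 replicate 3.

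The second comparison asked the same of the nandrolone rats. Calml3 rose by 4.01 ± 0.41 from day 7 to day 35 and Pcp4, a calmodulin-binding protein gene, by 3.15 ± 0.52. The day 7 signals of both, 16.2 and 23.8, are near background, and their changes were 4.95 and 3.90 with a pseudocount of 1 and 2.82 and 2.17 with 64. Fxyd6 rose by 2.70 ± 0.36, Cox7a1, the muscle form of a cytochrome oxidase subunit, by 2.08 ± 0.31 and Itga9 by 2.00 ± 0.28. Smaller rises were those of Gsta1, a glutathione transferase, by 1.89 ± 0.31, Ano1, a chloride channel, by 1.87 ± 0.28, Ablim1 by 1.65 ± 0.28, Ifitm10 by 1.57 ± 0.21 and Rcan2 by 1.45 ± 0.22. After quantile normalization, which takes out the shift of 0.20, these 10 genes still rose, by 3.77 for Calml3 and 1.34 for Rcan2. On the deposited scale a further probe set of Rcan2 stood at 0.82 and one of Ablim1 at 1.43, and neither passed. Of 18 alternatives run for single genes, Calml3 kept its call in 18, Pcp4 in 8, Ablim1 and Gsta1 in 9, Cox7a1 and Rcan2 in 13 and Fxyd6, Itga9, Ano1 and Ifitm10 in 15, with most losses on leaving out 1 array. Median centring ended the calls of Cox7a1, Gsta1 and Rcan2. Cox7a1 was called in vehicle rats too, at 1.45, and kept that call in 10 of 18 alternatives. A fit of only the 2 nandrolone groups, which is not among the 18, called 0 probe sets in limma, with 1016 at an unadjusted p under 0.05, so all 15 calls, that of Calml3 included, were lost there.

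Limma called 15 probe sets here, all higher, with 1789 at an unadjusted p under 0.05, and all 15 were separated between the days as 12.3% of probe sets were against 10% by chance. With the replicate number as a block, 39 passed, 33 of them higher. After quantile normalization 126 passed, 51 higher and 75 lower, with all 15 among them. Single arrays decided the count: it was 1 without nandrolone day 7 replicate 1, 1 without replicate 2, 1 without nandrolone day 35 replicate 1 and 34 without replicate 2.

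Of the fixed lists, 15 passed camera. Markers of Schwann cells and nerve were higher with a median of 1.03 over 8 genes, 3 of which were higher adjusted over the list alone, led by the myelin enzyme gene Cnp at 1.88 ± 0.35. Developmental muscle genes were lower with -1.08, denervation stress genes with -0.57 and atrophy ubiquitin ligases and FoxO genes with -0.38, where the ligase genes Trim63 and Fbxo32 stood at -0.88 ± 0.25 and -1.10 ± 0.39 and did not pass. These 4 calls were lost with an estimated correlation (adjusted p = 0.584 with an estimated correlation for each). Slow fibre genes and tendon markers had medians of -0.69 and -0.68 (adjusted p = 0.683 with an estimated correlation for both) and proteasome subunits -0.40 (adjusted p = 0.630 with an estimated correlation). The slow fibre and tendon calls were lost after quantile normalization (adjusted p = 0.168 and 0.0743), the slow fibre call also without nandrolone day 35 replicate 3, at -0.06, and the tendon call without nandrolone day 7 replicate 3, at -0.36. Clock genes had 0.18 and adipocyte markers 0.85 (adjusted p = 0.790 with an estimated correlation for both); 6 clock genes were higher adjusted over the list alone, led by Per2 at 1.89 ± 0.39. Smooth muscle markers had 0.97 and Notch signalling genes 0.31 (adjusted p = 0.936 with an estimated correlation for both). Macrophage markers had -0.34, ribosomal proteins -0.24, and oxidative phosphorylation and fatty acid oxidation genes -0.23 each (adjusted p = 0.965 with an estimated correlation for all 4). The oxidative phosphorylation list had a mean of 0.02 before the shift was taken off. Without nandrolone day 35 replicate 3 the relative median was 0.05 for oxidative phosphorylation and 0.06 for fatty acid oxidation genes, and the smooth muscle call was lost at 0.15; developmental muscle genes stood at -0.55, proteasome subunits at -0.19, atrophy genes at -0.13, Schwann markers at 0.53 and adipocyte markers at 0.13. Macrophage markers stood at -0.64, ribosomal proteins at -0.12, clock genes at 0.45 and Notch genes at 0.19 there, all still past camera. With quantile normalization and without that array the developmental muscle (adjusted p = 0.057), atrophy (0.0683), adipocyte (0.122) and Notch calls (0.0624) were lost, and of those kept none held with an estimated correlation (Schwann markers 0.52, adjusted p = 0.520 with an estimated correlation). Macrophage markers were at 0.11 without nandrolone day 7 replicate 3, and the clock call was lost without nandrolone day 35 replicate 1 at -0.01. The calls of ribosomal proteins, oxidative phosphorylation and fatty acid oxidation genes were lost after quantile normalization (adjusted p = 0.686, 0.895 and 0.262). In nandrolone day 35 replicate 3 the adipocyte score was 1.89 and the smooth muscle score 2.21, the highest of the 12 arrays. The rise of Schwann markers was not particular to nandrolone rats. In vehicle rats Cnp was called over all probe sets, at 1.85, and kept its call in 14 of 18 alternatives. The array score of the Schwann list rose by 0.62 in vehicle rats with no overlap between the days, though the list did not pass camera there.

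Both time comparisons shared 11 called probe sets, against 0.119 if calls were independent. Their changes use no array in common, but the estimate of a probe set's spread is shared by all groups. A probe set with a low shared spread is more easily called in both, so the calls are not independent. The excess over 0.119 therefore does not measure the agreement of the 2 comparisons. Of the 192 called in vehicle rats 191 had the same sign in nandrolone rats. Across probe sets the changes of the 2 comparisons correlated with a Pearson r of 0.575; genes are not independent replicates.

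The third comparison asked what nandrolone given from the day of surgery did by day 7. The list with the smallest p held immediate early genes, which respond within minutes to stimulation. Atf3, a stress-induced transcription factor, stood at -2.60 ± 0.83 with nandrolone, the nuclear receptor gene Nr4a1 at -1.87 ± 0.65, Egr2 at -1.90 ± 0.68 and Ier5 at -1.38 ± 0.35. After quantile normalization these were -2.70, -1.98, -2.01 and -1.48. The tendon markers Tnmd and Fmod stood at 1.57 ± 0.59 and 1.56 ± 0.60, and Ecrg4 at 1.64 ± 0.44, while the matrix genes Postn, Timp1 and Tnc stood at -0.14, -0.09 and -0.04. None of these passed, and the extracellular matrix list did not pass camera (relative median 0.10, adjusted p = 0.702).

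Limma called 0 probe sets in this comparison, and 161 of 18626 had an unadjusted p under 0.05. Every adjusted p was 1. Quantile normalization also gave 0 calls, with 331 at an unadjusted p under 0.05. When nandrolone day 35 replicate 3, which is in neither group, was left out as well, it gave 0 with 520. All these shares lie below the 0.05 that a test gives on average without any effect. The 0 calls therefore do not show that nandrolone had no effect. Immediate early and heat shock genes were lower as a set by camera, with a relative median of -0.98 over 16 genes, 15 of them below 0 (adjusted p = 5.79e-34; adjusted p = 0.0898 with an estimated correlation), and 0 were lower adjusted over the list alone. Their array score was -0.993 in nandrolone day 7 replicate 1, against 0.155 and -0.0872 in the other 2 nandrolone arrays and 0.477 to 0.965 in the vehicle arrays. Tendon and cartilage markers were higher by 0.80 (adjusted p = 0.996 with an estimated correlation). Their call was lost without nandrolone day 7 replicate 3, at 0.04, and without vehicle day 7 replicate 2, at 0.55, and their score of 1.04 in nandrolone day 7 replicate 3 was the highest of all arrays, as was that array's macrophage score of 1.39. Of the other lists past camera, which compares a list with all other genes, relative medians were -0.16 for fast fibre genes, -0.17 for denervation stress genes, -0.13 for glucocorticoid responsive genes, -0.13 for ribosomal proteins and -0.09 for oxidative phosphorylation genes (adjusted p = 0.996 with an estimated correlation for each). These 5 calls were lost after quantile normalization, which left 2 lists, and before the shift was taken off the medians of the oxidative phosphorylation and glucocorticoid lists were above 0. Of genes tied to atrophy and androgen action, Fbxo32 stood at -0.12 ± 0.39, Trim63 at -0.15 ± 0.25, Myog, a myogenic factor, at -0.04 ± 0.21, Igf1 at 0.23 ± 0.50 and Apod at 1.15 ± 0.91.

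The fourth comparison asked what nandrolone given from day 29 did by day 35. The gene with the largest change among those with the smallest p was Apod, a lipid carrier, at 3.89 ± 0.91 with nandrolone and 3.78 after quantile normalization. Matrix genes stood higher, with the adhesion modulator Tnc at 3.00 ± 1.11, Postn at 2.23 ± 0.77 and the protease inhibitor gene Timp1 at 2.11 ± 0.70. Mbp, the major protein of peripheral and central myelin, stood at 3.00 ± 0.86 and Sox18, an endothelial transcription factor, at 1.55 ± 0.35. Lower values were those of Mybph, a myosin-binding protein gene, at -0.88 ± 0.19 and Sgk1 at -0.85 ± 0.23. None of these passed over all probe sets. With quantile normalization and without nandrolone day 35 replicate 3, Apod stood at 2.51, Tnc at 1.27, Postn at 1.21, Timp1 at 1.09, Mbp at 1.56 and Sgk1 at -1.12.

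Limma called 0 probe sets, with 1445 at an unadjusted p under 0.05 and a smallest adjusted p of 0.602; quantile normalization gave 0 as well. Adjusted over the list alone, Apod, Mbp, Sox18, Met, Dlk1 and Alas2 were higher in their lists and Sgk1 lower. Extracellular matrix genes were higher as a set, with a relative median of 0.77 and all 42 genes above 0 (camera adjusted p = 2.01e-08). Higher by camera as well were adipocyte markers with 1.14, smooth muscle and pericyte markers 0.74, macrophage markers 0.57, endothelial markers 0.47, cell cycle genes 0.46, Schwann cell and nerve markers 0.39 and Notch signalling genes 0.25. Each of these 8 calls was lost with an estimated correlation (adjusted p = 0.711 with an estimated correlation for each). Nandrolone day 35 replicate 3 had the highest score of all 12 arrays for matrix genes at 1.52, Schwann markers at 1.49, endothelial markers at 1.20, adipocyte and smooth muscle markers. With quantile normalization and without that array, the relative median was 0.33 for matrix genes, 0.29 for macrophage markers and 0.28 for cell cycle genes, all still past camera (adjusted p = 0.675, 0.715 and 0.644 with an estimated correlation), while smooth muscle (-0.01), adipocyte (0.34), endothelial (0.10), Schwann (0.35) and Notch genes (-0.001) no longer passed. The Schwann and adipocyte lists missed by little (camera adjusted p = 0.0601 and 0.0833). On the deposited scale without that array both still passed camera, at 0.36 and 0.33 (adjusted p = 0.0108 and 0.024), while smooth muscle, endothelial and Notch genes did not. The cell cycle call was also lost with the 60% filter (0.07, adjusted p = 0.848). With quantile normalization and without that array developmental muscle genes (0.86, adjusted p = 2.37e-05), slow fibre genes (0.72, 2.05e-06), immediate early genes (0.36), fatty acid oxidation genes (0.17) and oxidative phosphorylation genes (0.10) were higher by camera, none of which passed with all arrays on the deposited scale. These calls were lost too (adjusted p = 0.463 with an estimated correlation for the first 2 lists and 0.645 for the other 3). The developmental and slow fibre values rest on 2 nandrolone arrays. The log2 signal in replicates 1 and 2 was 5.80 and 12.87 for Ankrd2, 10.71 and 13.15 for Myh3 and 8.59 and 11.84 for Casq2. Replicate 1 lay within or below the vehicle range for these 3 genes. The slow fibre score was -0.0894 in replicate 1 and 0.826 in replicate 2, against -1.02 to 0.167 under vehicle. The developmental score was 0.114 and -0.0943, in both above the vehicle scores of -1.07 to -0.221, so replicate 2 did not carry that list. Without vehicle day 35 replicate 3 the macrophage call was lost at 0.53, adipocyte at 0.97, smooth muscle at 0.71, endothelial at 0.45, Schwann at 0.65 and Notch at 0.30.

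The glucocorticoid responsive genes were lower with nandrolone at day 35, with a relative median of -0.52 over 20 genes (camera adjusted p = 4.26e-08; adjusted p = 0.711 with an estimated correlation), and -0.61 with quantile normalization and without replicate 3 (adjusted p = 0.0545 with an estimated correlation). Their members with the smallest p were Sgk1, Klf15 at -0.45 ± 0.22 and Cebpb at -0.55 ± 0.27. Atrophy ubiquitin ligases and FoxO genes were lower with -0.31, where Trim63 stood at -0.55 ± 0.25 and Foxo1 at -0.38 ± 0.26. Myogenic regulators had -0.34, clock genes -0.30, proteasome subunits -0.25, fast fibre genes -0.25, denervation stress genes -0.18, calcineurin and NFAT genes -0.17 and neuromuscular junction genes -0.16 (adjusted p = 0.711 with an estimated correlation for these 8 lists). Ribosomal proteins had -0.22 (adjusted p = 0.747 with an estimated correlation). Of these lists, proteasome subunits, ribosomal proteins and the fast fibre, denervation stress, calcineurin and neuromuscular junction genes had medians just above 0 before the shift was taken off, and the myogenic, neuromuscular junction, fast fibre, ribosomal, calcineurin, clock and denervation stress calls were lost after quantile normalization. Without nandrolone day 35 replicate 3 the neuromuscular junction median was 0.04, the proteasome call was lost at -0.07 (adjusted p = 0.151) and atrophy genes kept theirs at -0.16. Myogenic (-0.08), fast fibre (-0.10), clock (-0.20), calcineurin (-0.16) and denervation stress genes (0.01) lost their calls there too, while ribosomal proteins kept theirs at -0.14. The actin ratio separated the same 2 groups, as chance does in 10% of such comparisons, so a difference in RNA quality between them is not excluded.

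**Figure D2:**
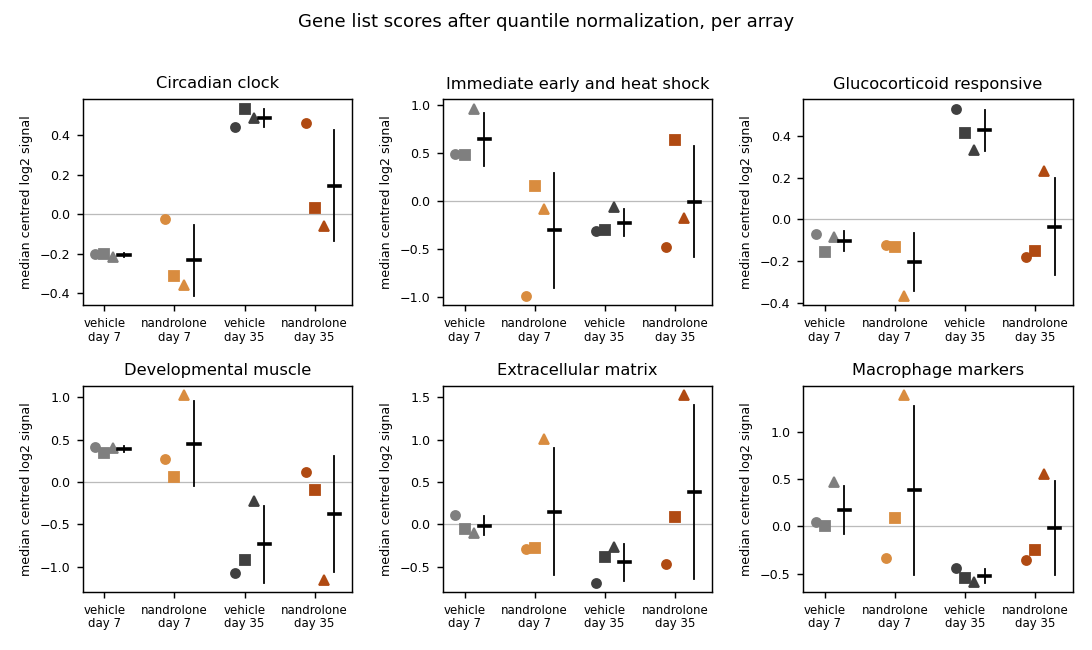
Array scores of 6 fixed gene lists, as the median over a list's genes of quantile-normalized log2 signal centred on each gene's mean over 12 arrays; circles, squares and triangles are replicates 1, 2 and 3, and the bar and line beside them are the group mean and SD (n = 3). Glucocorticoid scores were 0.332 to 0.53 in vehicle rats and -0.182 to 0.233 in nandrolone rats at day 35, and matrix scores were set apart by 1 array at 1.52.

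The interaction asked whether the effect of nandrolone differed between the 2 times. The genes that passed adjusted over the list alone were immediate early genes: Fos at 3.84 ± 1.32, Atf3 at 3.41 ± 1.18, Egr2 at 2.90 ± 0.97, Egr1 at 2.80 ± 0.94 and Ier2 at 1.95 ± 0.60. With quantile normalization and without nandrolone day 35 replicate 3, the day 35 effect on Atf3 was -0.17 against 0.82 with all arrays. These 5 of 16 genes did not pass over all probe sets. Values as large that passed neither way were those of Tnc at 3.04 ± 1.57, Apod at 2.74 ± 1.28 and Postn at 2.36 ± 1.09. Limma called 0 probe sets, with 311 at an unadjusted p under 0.05 and every adjusted p at 1, and 13 lists passed camera. Of 18626 probe sets, 311 is also a share below 0.05. Quantile normalization gave 0 calls with 745 at an unadjusted p under 0.05, and 920 without nandrolone day 35 replicate 3. The 0 calls therefore do not show that the effects were equal. Across probe sets the effects of nandrolone at day 7 and day 35 correlated with a Pearson r of 0.084, and with -0.171 without nandrolone day 7 replicate 3 and 0.307 without replicate 1 of that group. No probe set was called for nandrolone at either time, so none was shared.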

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

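The counts over other splits of the samples were planned before the results were seen; the tests of the 3 patterns weighed below were chosen after. The effect of nandrolone differed between day 35 and day 7 for 13 gene lists by a test of the interaction with camera, and that difference is why they are listed here. Immediate early and heat shock genes had the largest median interaction, 1.42 over 16 genes. Higher at day 35 than at day 7 in their response to the drug were also extracellular matrix genes (0.804), cell cycle genes (0.557), Notch signalling genes (0.359) and the markers of smooth muscle and pericytes (0.766), adipocytes (0.68), macrophages (0.476) and endothelium (0.416). Lower were tendon and cartilage markers (-0.755), glucocorticoid responsive genes (-0.142), atrophy ubiquitin ligases and FoxO genes (-0.124), clock genes (-0.0866) and proteasome subunits (-0.0761). All these medians include the shift of 0.13 over all probe sets; relative to it the glucocorticoid and clock medians were -0.27 and -0.22. After quantile normalization the tendon, glucocorticoid and clock calls were lost (adjusted p = 0.176, 0.0559 and 0.0702). None passed with an estimated correlation (adjusted p = 0.766 with an estimated correlation, and 0.837 for macrophage markers). The number of lists was 4 without nandrolone day 7 replicate 2, 7 without vehicle day 35 replicate 2, 8 without vehicle day 35 replicate 3 and 8 without nandrolone day 35 replicate 3. Without the last array the relative medians were 1.45 for immediate early, 0.269 for cell cycle, -0.358 for glucocorticoid and 0.211 for matrix genes, which kept their calls. Slow fibre (0.815), developmental muscle (0.624), oxidative phosphorylation (0.201) and fatty acid oxidation genes (0.157) passed camera there. None of them passed with all arrays on the deposited scale. With quantile normalization and without that array they passed camera too, at 0.728, 0.495, 0.123 and 0.157. None held there with an estimated correlation (camera adjusted p = 0.747 to 0.843). On the deposited scale without that array the calls lost were those of Notch (0.00255), smooth muscle (-0.0862), adipocyte (0.134), macrophage (0.0724), endothelial (-0.0666), tendon (-1.01), atrophy (-0.186), clock (-0.307) and proteasome lists (-0.0103). Of 100 splits of the samples, 42 gave as many lists (real 13, highest other 22) and 58 as many probe sets at an unadjusted p under 0.05 (real 311, highest other 6245), so chance is not excluded for the interaction. Splits were run on the deposited scale only. A split with so many probe sets may therefore reflect the unequal scale of the arrays, and a further structure of the samples was not tested.

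Matrix and stromal genes, 98 from the extracellular matrix, macrophage, adipocyte, endothelial and smooth muscle lists, stood higher with nandrolone at day 35; none of them is in another list. Unequal scaling is argued against as the whole cause, since their median was 0.658 after quantile normalization (bootstrap interval over genes 0.542 to 0.837). That interval resampled genes and not rats, so it leaves out the spread between rats. That one array carries the difference stays open: the score difference was 0.643 with all arrays and 0.184 without nandrolone day 35 replicate 3, whose score was 1.24 against -0.351 and 0.0719 in its group. A lower share of muscle fibre RNA, from the piece of muscle taken, may also raise these genes and stays open. Smooth muscle and tendon markers moved apart by 0.809 but varied as widely within the groups. That test held no fibre gene, so it cannot decide on fibre share. Nandrolone day 35 replicate 3 had the lowest score of all arrays for slow fibre (-1.4), developmental muscle (-1.16) and oxidative phosphorylation genes (-0.309). Its score was also lowest for neuromuscular junction (-0.768) and fatty acid oxidation genes (-0.618), but not for fast fibre (-0.00933) or glycolysis genes (-0.0459). These lows rest on that array alone, so they do not decide it either. Geometric mean signals under vehicle and nandrolone were 316.4 and 834.8 for Acta2, 66.1 and 293.1 for Adipoq and 179.2 and 372.2 for Csf1r. With quantile normalization and without replicate 3 the log2 differences were 0.46, 0.52 and 0.69. An effect of the drug on connective tissue is the biological explanation the design gives and was not separated from these 2.

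Clock genes differed between day 35 and day 7. Unequal scaling is argued against as the whole cause by the quantile-normalized array scores of the list. These were 0.443 to 0.534 in vehicle day 35 and -0.217 to -0.2 in vehicle day 7. Of the 17 genes 10 passed after quantile normalization, 7 higher and 3 lower, against 5 before. Calls over all probe sets rose too, from 192 to 1045, so that count does not weigh on scaling. A different hour of tissue collection at the 2 times could give such opposite movements and cannot be told apart from an effect of time after nerve section, because the labels give no hour. Nor can age be told apart from it, because no innervated muscle was sampled. In the nandrolone rats the 7 genes placed in a repressor and output arm exceeded the 3 of the activator arm by 1.52, and in the vehicle rats by 2.25, so the pattern was present under both treatments, as a shared hour or a shared effect of time would give. The other clock genes were in neither arm. In nandrolone rats these ran from -0.83 for Rora to 0.97 for Bhlhe41, with Cry1 at 0.05, Hlf at 0.15 and Bhlhe40 at -0.15.

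Immediate early and heat shock genes stood lower with nandrolone at day 7. The difference in scores was -0.954 with all arrays and -0.611 without nandrolone day 7 replicate 1, which argues against that array as the whole cause. Their median after quantile normalization was -0.978 (bootstrap interval over genes -1.98 to -0.426), which argues against scaling as the whole cause. That interval resampled genes and not rats, so it leaves out the spread between rats. These genes respond within minutes, so differences in handling between animals may explain the values: the scores ranged over 1.12 within nandrolone day 35, but over 0.488 within vehicle day 7 and 0.245 within vehicle day 35, so the tests do not decide this. An effect of the drug stays open beside it.

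For the other comparisons 3 arrays against 3 make 10 splits, too few for a share under 0.05. For time under vehicle 1 of 10 splits gave as many called probe sets (real 192, highest other 0) and 3 as many lists (real 11, highest other 13). For time under nandrolone these were 1 split (real 15, highest other 2) and 5 splits (real 15, highest other 17). For nandrolone at day 7, 5 splits gave as many probe sets at an unadjusted p under 0.05 (real 161, highest other 532) and 9 as many lists (real 7, highest other 17). For nandrolone at day 35 these were 3 splits (real 1445, highest other 7805) and 2 splits (real 18, highest other 20). These splits too were run on the deposited scale, where array medians at day 35 ranged from 44.8 to 111. The split with 7805 may therefore reflect unequal scale, and a further structure other than treatment was not tested.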

How the results depend on the processing

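Chosen after seeing the data were the alternatives that pair quantile normalization with weights, with the block or with leaving nandrolone day 35 replicate 3 out, and the one that leaves that array out of the shared spread. The cause of the changes below was not tested, except that fewer arrays or fewer genes go into some fits by construction. Called probe sets for time under vehicle, 192, were 1045 after quantile normalization, 899 after median centring, 495 with the replicate block, 586 at an adjusted p of 0.10, 1267 with only the 2 groups in the fit, 877 with the array out of the shared spread, 2030 with quantile normalization without it and 1294 with block and quantile; leaving out 1 array gave 13 to 238. For time under nandrolone, 15, they were 126, 101, 39, 41 and 0 under the first 5 of these (in the limma fit with 0 calls, 1016 had an unadjusted p under 0.05), 101 with quantile normalization without the array, 128 with block and quantile, 9 without a filter and 25 with the 60% filter; leaving out 1 array gave 1 to 34. Array quality weights did not converge on the deposited scale, and their counts of 8414 and 4058 for time, 13798 for nandrolone at day 35 and 3432 for the interaction are not read as calls; after quantile normalization weights gave 5274, 293, 49 and 0. Leaving out 1 array gave 0 to 2 for nandrolone at day 7 (2 without vehicle day 7 replicate 3), 0 to 1 at day 35 (1 without nandrolone day 35 replicate 3) and 0 for the interaction. Lists past camera for nandrolone at day 7, 7, were 2 after quantile normalization, 2 with block and quantile, 3 with quantile without the array, 1 with weights and quantile, and 3 to 13 leaving out 1 array (3 without vehicle day 7 replicate 3, 13 without nandrolone day 7 replicate 2). For nandrolone at day 35, 18, they were 7 with weights, 11 with quantile without the array and 6 (without vehicle day 35 replicate 3) to 23; for time under vehicle, 11, they were 9 to 14; for time under nandrolone, 15, they were 9 with quantile without the array and 14 to 18; for the interaction, 13, they were 7 with quantile without the array, 8 with weights and quantile and 4 to 17. Direction below is the one camera gave, which a list's median need not follow, so some relative medians kept the sign of the main value. Turned lists passed camera only in time under nandrolone. These were slow fibre and fatty acid oxidation genes with weights, and oxidative phosphorylation genes with weights, with weights and quantile, and with quantile without the array. Changes of direction by camera, as relative medians, came with weights for proteasome subunits (-0.0183), denervation stress genes (0.41), ribosomal proteins (-0.143) and adipocyte markers (-0.238) at day 35, with Psmc1 (0.224) and Cfd (-0.505), for slow fibre (0.441), oxidative phosphorylation (0.207) and fatty acid oxidation genes (0.307) in time under nandrolone, and for proteasome subunits (0.101) and macrophage (-0.0665), adipocyte (-0.449) and tendon markers (-0.0181) in the interaction. With weights and quantile they came for denervation stress genes at day 35 (0.197), ribosomal proteins in time under vehicle (0.0353), slow fibre (-0.0204), oxidative phosphorylation (0.154) and fatty acid oxidation genes (0.143) in time under nandrolone, and adipocyte (-0.214) and tendon markers (-0.299) in the interaction. The 60% filter turned cell cycle genes at day 35 (0.0692), in time under vehicle (0.0872) and in the interaction (-0.0652). Quantile normalization, alone and with the block, turned ribosomal proteins in time under vehicle (0.0309) and oxidative phosphorylation genes in time under nandrolone (-0.0436). Quantile normalization without the array turned neuromuscular junction genes at day 35 (0.0204), ribosomal proteins in time under vehicle (0.0309), slow fibre (0.0123), oxidative phosphorylation (0.114) and fatty acid oxidation genes (0.123) in time under nandrolone and smooth muscle markers in the interaction (-0.0365). Leaving out 1 array gave ranges that change direction for neuromuscular junction genes at day 35 (-0.501 to 0.0441), oxidative phosphorylation (-0.419 to 0.0511) and fatty acid oxidation genes (-0.536 to 0.0632) in time under nandrolone and endothelial markers in the interaction (-0.0666 to 0.652), each turned without nandrolone day 35 replicate 3; for macrophage markers in time under nandrolone (-0.693 to 0.11), turned without nandrolone day 7 replicate 3; and for macrophage markers in the interaction (-0.0759 to 0.834), turned without nandrolone day 7 replicate 1. The counts of 0 for nandrolone at day 7, at day 35 and for the interaction stayed 0 by limma (161, 1445 and 311 at an unadjusted p under 0.05) under both pseudocounts, both filters, quantile normalization, median centring and the block. Of signals per array 17.5 to 29.3% lay under 16, where changes depend on the pseudocount. In simulated data with 200 changed probe sets 2 to 8% of 2-fold changes were recovered on the deposited scale and 12 to 24% after quantile normalization, and 13 to 20% on data simulated without array offsets.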

Other observations

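The genes and the test in this part were chosen after their values were seen. Some glutathione transferases, which attach glutathione to reactive compounds, were among the genes that rose under vehicle between day 7 and day 35. Of 17 tested genes of the family 3 were called higher, Gsta1 at 1.76, Gstm2 at 1.58 and Gstm7 at 1.51, and 0 lower, against 79 higher of 10425 genes in all. Others stood lower without passing, Gstt1 at -1.15, Mgst2 at -0.92 and Gstt2 at -0.78, and after quantile normalization 5 were called higher and 2 lower. The family was picked because its members were seen among the called genes, so these counts test nothing. Nqo1, a quinone reductase, rose by 1.25 ± 0.27 and the exporter gene Abcc1 by 1.65 ± 0.29 in the same comparison. Ky, a muscle gene of the Z disc, rose by 2.09, Sspn, a membrane protein of muscle, by 1.24 (3 of its 5 probe sets passed), and Timp3, an inhibitor of matrix proteases, by 1.65 (1 of its 4).

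A hypothesis formed from these data is that nandrolone keeps glucocorticoid responsive genes below their level in vehicle rats at day 35. The array scores of the list were 0.53, 0.416 and 0.332 in vehicle rats and -0.182, -0.153 and 0.233 in nandrolone rats, a difference of -0.46, with no overlap between the groups, which chance gives in 10% of such comparisons. The exact permutation p was 0.1 (two-sided), the smallest that 3 against 3 arrays can give, so the hypothesis stays open. The actin 3' to 5' ratio also separated these 2 groups, so a difference in RNA quality is not excluded.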
